A study of Homo sapiens with 16 samples.

How the data were processed

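Per the labels' protocols, IMR90 cells were grown in DMEM with 10% serum at 3% oxygen and passaged until growth ceased, and senescent cells were kept for 2 more weeks. Total RNA (1 µg) was depleted of ribosomal RNA, made into stranded libraries with the ScriptSeq v2 kit and sequenced on an Illumina NextSeq, and only forward reads of 48 bases were used. The CBP and luciferase hairpins were carried by lentivirus and selected with puromycin in cells already senescent. Per the submitters' processing notes, reads were trimmed with Trimmomatic, aligned to hg19 (GRCh37) with STAR, handled with SAMtools and counted per gene with featureCounts, whose versions are not given in the sources used here. The notes name edgeR for the samples of the CBP table as well. The deposited counts, whole numbers for 27135 genes in each of the 2 tables (13 and 3 libraries), were the starting point, and no column was left without a sample. Reads were not used here.

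The choices in this paragraph were made before the data were examined. The 13 libraries of the larger table were fitted together by edgeR's quasi-likelihood method with 6 groups and TMM scaling, after edgeR's filter on low counts by group, which left 17549 genes. The CBP table was fitted alone (14453 genes) with 2 knockdown libraries and 1 control, assumed to vary like the knockdown libraries. Benjamini-Hochberg adjusted p under 0.05 was the threshold, all tests were two-sided, and standard errors are the absolute log2 fold change over the square root of the F statistic. CPM values are counts scaled by edgeR to a library total of 1e6 with the TMM-scaled library sizes, and standard deviations are between replicates. The mean effect of the p300 hairpins was the average of both contrasts. Shared genes between comparisons were set against independence, and the covariance and correlation of fold changes against 20 simulations with no true change and the same shared controls.

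Gene lists written before the data were examined were tested by camera with a preset correlation of 0.01 and with an estimated correlation, and by fry, on log CPM with a prior count of 2. Fry tests whether a list's genes move to one side on balance and does not compare them with other genes. There were 19 pathway lists, 5 lists of cell-type markers and 1 quality list of mitochondrially encoded mRNAs, of which 0 members were in the tables. The lists share members, among them CXCL10 (NF-kB and interferon), CDKN1A (kinase inhibitors and p53) and GDF15.

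Genes were named by a rule. EP300, CREBBP, CDKN2A, CDKN1A, LMNB1, IL6 and MKI67 were given in each comparison. Then came the 6 largest increases and 6 largest decreases among genes past the threshold with a mean of at least 2 on the log2 CPM scale, no overlap between the groups' libraries and no clone-type or small-RNA symbol, and up to 3 members of each list with the smallest adjusted p, at most 30 genes in all per comparison. Names from the blocked fit and from genes with few shared stretches were chosen after the data had been seen.

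Replicate numbers were checked for pairing by correlating, over genes, each library's deviation from its arm's mean. In the p300 arms the numbers pair, with the correlations 0.769, 0.718 and 0.723. In the untreated arms the correlation was 0.201 in 1 pair of arms and population doublings differ (29 and 34 against 78 and 79), so there the numbers were taken as numbers only. A fit with blocks in the p300 and untreated arms was planned, and one with blocks in the p300 arms only was added after the data had been seen.

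Each gene's 48-base stretches were compared with those of 58721 genes of the GENCODE release 29 annotation on GRCh38, to find genes whose reads match elsewhere (few shared: up to 5%; many: over 50%). The build of the reference differs from that of the counts, and 91.4% of the genes were matched, 24314 by symbol and 487 by an older symbol. Hairpin targets were searched in the same annotation. Trends of gene length and GC content were removed with splines of 4 degrees of freedom as an alternative. Other alternatives were the DESeq2 test, upper-quartile and RLE scaling, no filter on low counts or a filter at 1 CPM in 2 libraries, a threshold of 2-fold, the 50 highest-count genes left out, only the compared groups, and leaving out each library in turn. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

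In a self-test, 200 genes were given changes of known size in counts simulated from the fitted means and dispersions. Of those changed 2-fold, 4-fold and 8-fold, the fit called 0%, 20.9% and 75.8% for replicative senescence, 3.0%, 65.7% and 83.3% for irradiation, and 0%, 26.9% and 78.8% for hairpin 1 (13.4%, 83.6% and 100% with blocks). For hairpin 2 with blocks they were 11.9%, 85.1% and 100%, for the mean with blocks 17.9%, 95.5% and 100%, and for CBP 0%, 22.4% and 63.6%. With blocks, 12 of 143 calls were false for hairpin 1, 6 of 137 for hairpin 2 and 11 of 153 for the mean. Without blocks they were 2 of 66 for replicative senescence, 3 of 104 for irradiation and 3 of 73 for hairpin 1. For CBP 21 of 78 calls were false. Scaling factors ranged from 0.846 to 1.27. Floors and counting errors cover counting only.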

Results

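Gene expression was measured by RNA sequencing in IMR90 cells, a line of human lung fibroblasts, in 16 libraries of 8 groups. One count table held 13 libraries: 2 of proliferating cells, 2 of cells in replicative senescence (the arrest reached after long passage), 2 of senescent cells carrying a control vector, 2 each of senescent cells carrying p300 shRNA 1 or p300 shRNA 2, and 3 of cells made senescent by irradiation. A second table held 3 libraries of senescent cells, 1 with a hairpin against luciferase and 2 with a hairpin against CBP. p300 (gene EP300) and CBP (gene CREBBP) are related histone acetyltransferases, and the series asked what p300 does to enhancers and transcription in senescence. Total counts were 34790674 and 39082184 in proliferating, 52048590 and 45018891 in replicatively senescent, and 37359903 and 30167569 in control vector libraries. They were 32903279 and 28596905 with hairpin 1, 36414412 and 24632505 with hairpin 2, 43648894, 45202571 and 42305503 after irradiation, 26103636 with the luciferase hairpin and 21015207 and 20373785 with the CBP hairpin. Replicates of the proliferating, senescent and p300 groups are labelled with different population doublings and those of irradiation with the same, and none is stated to be a separate culture, so the p-values measure a spread between samples or passages that may be technical.

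EP300, the gene targeted by the p300 hairpins, lies on chromosome 22. It was counted at 70.2 and 35.6 CPM (counts scaled to a common library total, as stated in the processing) in the proliferating libraries, 91.6 and 26.6 CPM in replicative senescence, 139.7 and 24.3 CPM with the control vector, 89.5 and 34.8 CPM with hairpin 1, 63.6 and 10.0 CPM with hairpin 2, and 38.5, 72.4 and 39.4 CPM after irradiation. In the other table it stood at 166.5 CPM with the luciferase hairpin and at 174.0 and 127.9 CPM with the CBP hairpin. CREBBP, the target of the CBP hairpin, was counted at 80.4 CPM in the luciferase library and at 56.3 and 43.6 CPM in the CBP libraries. The replicates of the p300 arms differed by several-fold in EP300 in the same way, so each knockdown was set against the control vector library of its own number. With hairpin 2, EP300 stood at 45.6% and 41.2% of its control (log2 ratios -1.13 and -1.28, counting errors 0.04 and 0.10). With hairpin 1 it stood at 64.1% in replicate 1 and at 143% in replicate 2 (log2 ratios -0.64 and 0.52, counting errors 0.03 and 0.07). The library labelled p300 shRNA 1 replicate 2 thus held more EP300 mRNA than its control, and every value of hairpin 1 rests in part on it.

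**Figure D1:**
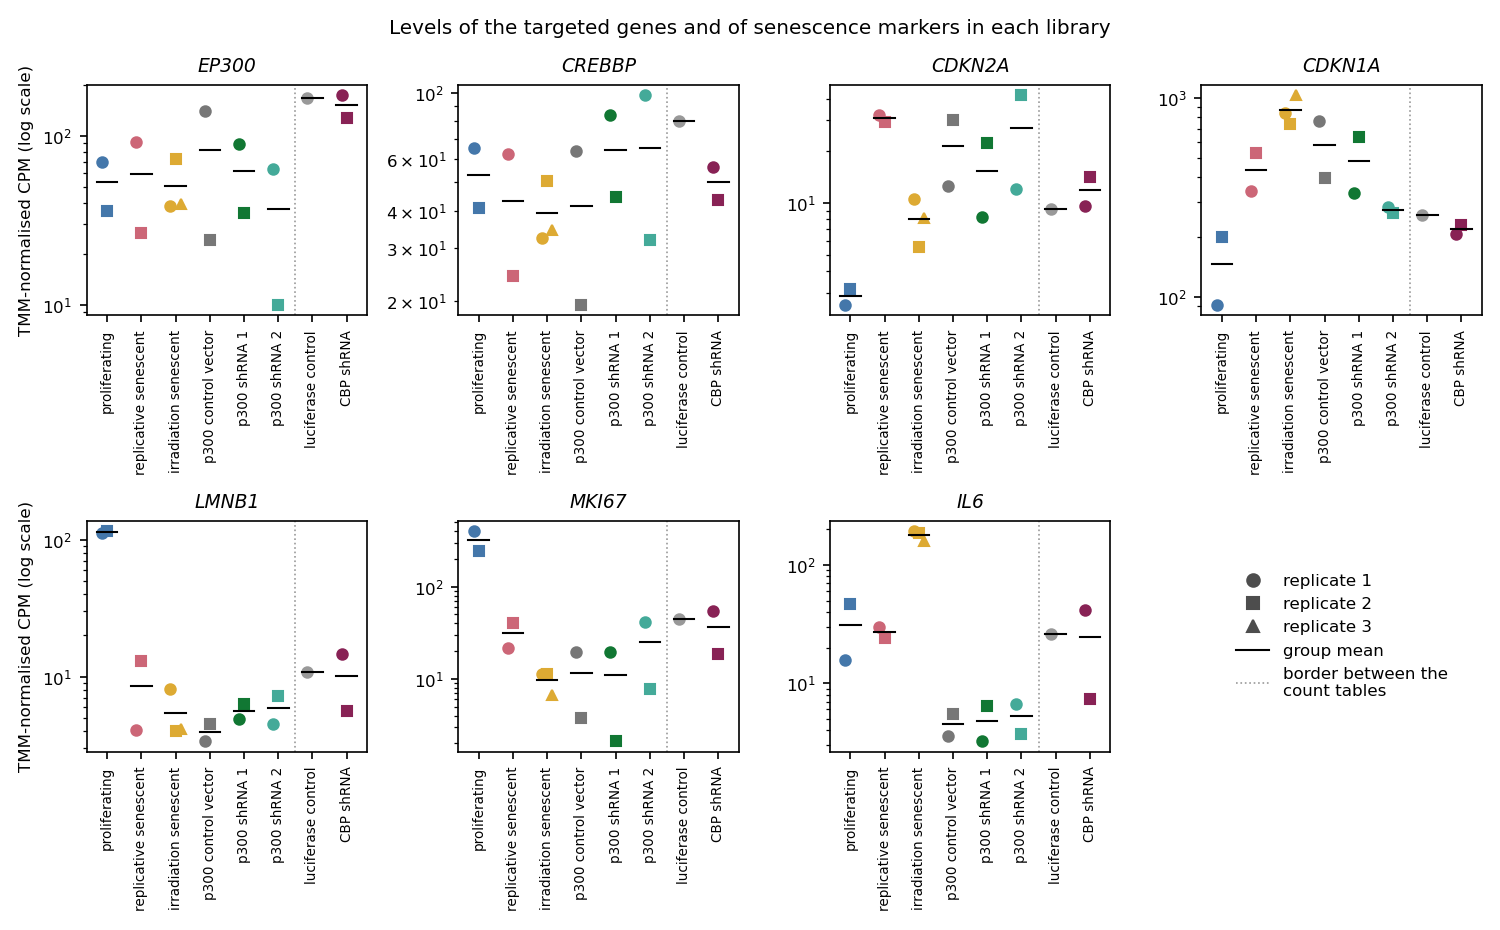
CPM on a log axis of EP300, CREBBP, CDKN2A, CDKN1A, LMNB1, IL6 and MKI67 in each of the 16 libraries, with marker shapes for the replicate number, a black line at each group's mean and a dotted line between the 2 count tables. CDKN2A stood near 30.8 CPM in replicative senescence and 2.86 CPM in proliferating cells.

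Replicatively senescent cells were compared with proliferating cells to describe the arrest that the p300 experiment starts from. The replication licensing genes MCM3 and MCM7, the mitotic kinesin KIF11 and checkpoint kinase BUB1B, and most replication-dependent histone genes fell. MCM3, MCM7 and KIF11 lost their calls without replicative senescence replicate 1, and the mitosis, replication and histone lists did not hold with an estimated correlation. CDKN2A, which encodes the cell-cycle inhibitor p16, rose, and LMNB1, which encodes the lamina protein lamin B1, fell. CDKN2A lost its call in each fit with 1 library left out, and LMNB1 without replicative senescence replicate 1. Such fits leave a single library in a group, so the losses cannot show how far the calls rest on it. The log2 fold change of CDKN2A was 3.24 to 3.58 with 1 library left out, and that of LMNB1 -3.13 without replicative senescence replicate 1. The interferon-stimulated genes OAS1, OAS2 and SAMD9L rose, although their list did not hold with an estimated correlation either. The inflammatory cytokine gene IL6 did not pass the test.

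CDKN2A stood at 30.8 ± 2.11 CPM in senescent and 2.86 ± 0.432 CPM in proliferating cells (SD, n = 2 each; log2 fold change 3.42, SE 0.69, adjusted p = 0.0197 by edgeR). LMNB1 fell from 113 ± 1.99 to 8.55 ± 6.37 CPM (log2 fold change -3.73, SE 0.57, adjusted p = 0.00708). CDKN1A, which encodes the p53-driven inhibitor p21, stood at 433 ± 131 against 145 ± 76.7 CPM and did not pass (log2 fold change 1.58, SE 0.50, adjusted p = 0.102), and neither did the proliferation marker MKI67 (log2 fold change -3.36, SE 1.09, adjusted p = 0.111). IL6 stood at 26.9 ± 4.03 against 31.1 ± 21.9 CPM (log2 fold change -0.21, SE 0.50, adjusted p = 0.877), and EP300 (0.16 (SE 0.95)) and CREBBP (-0.30 (SE 0.67)) did not pass. The largest increases were in TMEM178B (from 2.52 to 283 CPM), the D-type cyclin CCND2 (from 27.6 to 1826 CPM), the muscle ankyrin-repeat gene ANKRD1 (from 4.65 to 298 CPM), ELMOD1, TRIM58 and COBLL1, with log2 fold changes between 4.57 and 6.81. The largest decreases were in the glutamate receptor GRIA4 (from 59.8 to 0.686 CPM), the scavenger receptor COLEC12, TMEM119, the Notch ligand DLL4, the Wnt receptor ROR2 and the histone gene HIST1H2AJ, with log2 fold changes between -6.44 and -4.67. HIST1H2AJ shares 83.8% of its 48-base stretches with other genes and its value is uncertain.

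Of 46 mitosis genes, 31 fell and 0 rose at an adjusted p under 0.05 over all genes, and 0 rose and 45 fell when adjusted over the list alone (KIF11 -2.93 (SE 0.37), BUB1B -2.99 (SE 0.43), TTK -2.95 (SE 0.45)). Of 41 replication-dependent histone genes, 34 fell and 0 rose (39 lower adjusted over the list alone), among them HIST1H2AM (-3.42 (SE 0.36)), HIST1H2AH (-3.55 (SE 0.40)) and HIST1H2AG (-3.57 (SE 0.43)). Of 46 DNA replication genes, 27 fell (37 lower and 1 higher adjusted over the list alone), among them the epigenetic maintenance factor UHRF1 (-2.31 (SE 0.28)), MCM3 (-2.24 (SE 0.31)) and MCM7 (-2.57 (SE 0.38)). Of 34 nuclear lamina and chromatin genes, 10 fell and 0 rose (14 adjusted over the list alone), with the condensin subunit SMC4 at -2.43 (SE 0.33), the histone methyltransferase EZH2 at -2.75 (SE 0.41) and LMNB1. Of 41 interferon-stimulated genes, 17 rose and 0 fell (26 higher and 1 lower adjusted over the list alone): OAS2 rose from 0.328 ± 0.0106 to 19.3 ± 2.54 CPM, SAMD9L from 36.6 ± 0.488 to 212 ± 82.5 CPM, and OAS1 from 0.0512 to 12.3 CPM. The medians of these 5 lists were -2.79, -3.40, -1.83, -0.78 and 1.60. Camera's adjusted p with a preset correlation was 2.63e-35, 2.21e-34, 5.82e-27, 5.42e-09 and 9.06e-19 in that order. None of these set calls held with an estimated correlation: the adjusted p = 0.111 with an estimated correlation for mitosis and 0.0657 for the other 4, while fry's adjusted p for a movement to one side was between 9.39e-04 and 0.00345.

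Of 8 cyclin-dependent kinase inhibitor genes, 1 rose and 1 fell (2 and 3 adjusted over the list alone), CDKN2A and the gene CDKN2C (-3.20 (SE 0.58)). Of 33 secreted cytokine and chemokine genes, 0 rose and 2 fell (also when adjusted over the list alone), IL1B (-4.46 (SE 1.10)) and the neutrophil attractant CXCL5 (-2.34 (SE 0.51)), each of which lost its call in 3 of the 4 fits with 1 library left out, with a list median of -0.32 and a camera adjusted p of 0.734. Of 25 secreted protease, inhibitor and IGF-binding protein genes, 1 rose, IGFBP7 (1.65 (SE 0.37), 2 higher and 1 lower adjusted over the list alone). Of 23 NF-kB targets, 1 rose and 1 fell (1 and 2 adjusted over the list alone), and of 29 p53 targets 2 rose, the metabolic regulator TIGAR (2.00 (SE 0.28)) and the polymerase POLH (1.24 (SE 0.27); 4 higher adjusted over the list alone). The p53 list had a camera adjusted p = 6.92e-04, which was lost (adjusted p = 0.553 with an estimated correlation). Extracellular matrix genes had 2 of 35 lower, ELN (-2.91 (SE 0.59)) and FBN2 (-2.66 (SE 0.65)), with 1 higher and 7 lower adjusted over the list alone, a camera adjusted p = 0.00209 and an adjusted p = 0.893 with an estimated correlation. Unfolded protein response genes had 1 of 27 lower (3 adjusted over the list alone; median -0.71, camera adjusted p = 0.00576, adjusted p = 0.238 with an estimated correlation). Lung fibroblast markers had 0 of 16 called, also when adjusted over the list alone (median -1.03, camera adjusted p = 0.00576, adjusted p = 0.199 with an estimated correlation). For 6 other lists camera gave no call: 1 of 20 acetyltransferase and bromodomain genes fell, ATAD2 (-1.84 (SE 0.35)), 2 of 24 contractile and YAP targets rose, 0 of 27 cholesterol genes and 0 of 31 ribosome biogenesis genes passed, 1 of 38 lysosome genes rose, and 2 of 29 immediate early genes rose, EGR2 (3.71 (SE 0.51)) and DUSP6 (1.63 (SE 0.37)). Of 21 NRF2 targets, 4 fell and 0 rose. Of the other cell-type markers, 2 of 12 epithelial and 1 of 7 leukocyte genes fell, 0 of 6 endothelial genes passed, and 1 of 9 smooth muscle genes rose and 1 fell.

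Across 17549 tested genes, 324 were higher and 504 lower in replicative senescence (828 in all, by edgeR's quasi-likelihood test), against 1989 by DESeq2. At an unadjusted p under 0.05 there were 3321 genes, where 877 are expected by chance. Each of the 4 fits that leave out 1 of these libraries keeps a single library in its group. Calls are then lost through fewer libraries alone, so the counts cannot show how far the calls rest on the library left out. The log2 fold change of CDKN2A stayed at 3.24 to 3.58 in these fits. CDKN2A, POLH and ELN lost their calls in each of these 4 fits. Without replicative senescence replicate 1, LMNB1, ANKRD1, TMEM119, ROR2, HIST1H2AJ, HIST1H2AG, UHRF1, MCM3, MCM7, KIF11, TTK, SMC4, EZH2, CDKN2C, TIGAR, EGR2, CXCL5, IL1B, IGFBP7, ATAD2, FBN2 and DUSP6 also lost theirs. CXCL5, IL1B, IGFBP7, ATAD2, FBN2 and DUSP6 lost them without replicative senescence replicate 2 as well, ANKRD1, ATAD2, FBN2 and DUSP6 without proliferating replicate 1, and CDKN2C, CXCL5, IL1B and IGFBP7 without proliferating replicate 2, where IL1B stood at a log2 fold change of -1.25, CXCL5 at -1.57 and CDKN2C at -2.40. FBN2 stood at -1.32 without proliferating replicate 1, and LMNB1 at -3.13 without replicative senescence replicate 1. In the fit without replicative senescence replicate 1, TMEM178B, CCND2, GRIA4, DLL4, OAS1, OAS2, SAMD9L and BUB1B kept theirs.

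Cells made senescent by irradiation were compared with the same proliferating cells to describe an arrest set off by DNA damage. Most mitotic, replication and histone genes on the lists fell, although none of these lists held with an estimated correlation (adjusted p = 0.232 with an estimated correlation), and CDKN1A rose. Some genes of the senescence-associated secretory phenotype (secreted inflammatory factors) rose, among them IL6, the chemokines CXCL5 and CCL20, the growth factor AREG and the matrix metalloprotease MMP3. The fibroblast matrix genes COL3A1 and LUM fell. The cytokine, protease and matrix lists did not hold with an estimated correlation either.

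CDKN1A stood at 869 ± 149 CPM after irradiation (SD, n = 3) and 145 ± 76.7 CPM in proliferating cells (n = 2; log2 fold change 2.58, SE 0.49, adjusted p = 0.00346 by edgeR), and IL6 at 179 ± 17.5 against 31.1 ± 21.9 CPM (log2 fold change 2.53, SE 0.51, adjusted p = 0.00454). LMNB1 (-4.38, SE 0.50, adjusted p = 2.48e-04) and MKI67 (-5.02, SE 0.99, adjusted p = 0.00418) fell. CDKN2A stood at 8.06 ± 2.50 CPM and did not pass (log2 fold change 1.49, SE 0.61, adjusted p = 0.0845), and with length and GC trends removed it stood at 4.29, 3.30 and 2.99 CPM after irradiation against 3.59 and 2.50 CPM in proliferating cells. Neither EP300 (-0.08 (SE 0.87)) nor CREBBP (-0.43 (SE 0.61)) passed. The gene-naming rule gave among the largest increases SLC25A6, CD99, NBPF11, SMG1P1 and MTRNR2L9. SLC25A6 (at least 4202-fold) had 0 counts in proliferating libraries, with a floor of 3 counts over the group, and CD99 had 1 count. SLC25A6 and CD99 share all of their 48-base stretches with other genes, NBPF11 74.6% and SMG1P1 98.9%, and the values of these 4 genes are uncertain. The largest decreases were in GRIA4 (-6.05 (SE 0.46)), TMEM119 (-6.02 (SE 0.68)), the linker histone genes HIST1H1D and HIST1H1B, the collagen gene COL14A1 (-5.41 (SE 0.84)) and the pseudogene ATP5EP2. Among genes with few shared stretches, a choice made after the values were seen, the largest increases included AREG (from 0.272 to 64.9 CPM), CCL20 (from 0.332 to 65.1 CPM), the transcription factor EHF (6.77 (SE 0.71)), the splicing factor SRSF10 (6.57 (SE 0.71)) and MMP3 (from 0.952 to 86.1 CPM).

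Of 33 secreted cytokine and chemokine genes, 20 rose and 1 fell (22 and 1 adjusted over the list alone), with CXCL5 at 5.06 (SE 0.52). The list median was 2.53 and camera's adjusted p 3.14e-08, which was lost (adjusted p = 0.0846 with an estimated correlation). Of 25 secreted protease genes, 7 rose and 0 fell, also when adjusted over the list alone (median 1.17; camera adjusted p = 0.0131, adjusted p = 0.745 with an estimated correlation). Of 23 NF-kB targets, 6 rose and 1 fell, also when adjusted over the list alone, among them IRAK2 (1.78 (SE 0.30)) and CXCL10 (3.18 (SE 0.66)), the latter also a member of the interferon list (median 0.76; camera adjusted p = 0.0390, adjusted p = 0.232 with an estimated correlation). Of 41 interferon-stimulated genes, 13 rose and 0 fell (17 and 1 adjusted over the list alone), among them OAS2 (3.56 (SE 0.39)), OAS1 (6.07 (SE 0.74)) and IRF7 (2.56 (SE 0.36); median 1.04; camera adjusted p = 0.00142, adjusted p = 0.373 with an estimated correlation). Of 29 p53 targets, 10 rose and 1 fell, also when adjusted over the list alone, among them SERTAD1 (2.51 (SE 0.38)) and TIGAR (1.56 (SE 0.26); camera adjusted p = 0.00221, adjusted p = 0.455 with an estimated correlation). Fry's adjusted p for these 5 lists was 2.74e-05, 0.111, 0.00119, 0.00155 and 0.0103. CXCL10 lost its call without proliferating replicate 2.

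Of 46 mitosis genes, 40 fell and 0 rose (44 adjusted over the list alone), among them KIF11 (-4.23 (SE 0.34)), KIF23 (-3.39 (SE 0.28)) and BUB1B (-4.27 (SE 0.38)). Of 41 histone genes, 33 fell and 0 rose (36 adjusted over the list alone), with HIST1H2AH at -4.59 (SE 0.36). Of 46 replication genes, 33 fell and 0 rose (36 adjusted over the list alone), with the clamp loader gene RFC3 at -2.72 (SE 0.30) and the polymerase gene POLA1 at -2.58 (SE 0.30). Of 34 nuclear lamina and chromatin genes, 17 fell and 0 rose, also when adjusted over the list alone, with SMC4 at -3.55 (SE 0.30). Of 20 acetyltransferase and bromodomain genes, 1 rose, KAT2A (1.70 (SE 0.32)), and 6 fell (1 and 7 adjusted over the list alone), among them HAT1 (-1.50 (SE 0.21)) and ATAD2 (-2.20 (SE 0.30)). Camera's adjusted p for these 5 lists was 8.21e-23, 1.19e-16, 1.05e-12, 1.84e-06 and 0.00936, and for each of them it was lost (adjusted p = 0.232 with an estimated correlation). Of 35 extracellular matrix genes, 11 fell and 0 rose, also when adjusted over the list alone, with COL3A1 at -2.64 (SE 0.42) and the proteoglycan LUM at -3.10 (SE 0.55) (median -1.32; camera adjusted p = 2.85e-04, adjusted p = 0.602 with an estimated correlation). Of 24 contractile and YAP targets, 3 rose and 7 fell (3 and 8 adjusted over the list alone), with CNN2 at -1.76 (SE 0.28) (median -0.82; camera adjusted p = 0.0324, adjusted p = 0.285 with an estimated correlation). Of 16 lung fibroblast markers, 6 fell and 0 rose (7 adjusted over the list alone), with PDGFRA at -3.36 (SE 0.58) and DCN at -2.69 (SE 0.59) (camera adjusted p = 0.0111, adjusted p = 0.232 with an estimated correlation). DCN lost its call without proliferating replicate 1 (-1.96). Members of the other lists went both ways without a camera call: 1 of 8 kinase inhibitors rose and 2 fell, 2 of 27 cholesterol genes rose and 3 fell, 5 of 38 lysosome genes rose and 2 fell, 1 of 27 unfolded protein response genes rose and 8 fell, 1 of 21 NRF2 targets rose and 5 fell, 7 of 29 immediate early genes rose and 5 fell (FOS -4.63 (SE 0.70)), and 6 of 31 ribosome biogenesis genes rose and 10 fell. Of the marker lists, 1 of 12 epithelial genes fell, 0 of 6 endothelial genes passed, 3 of 7 leukocyte genes rose, each under 1 CPM, and 1 of 9 smooth muscle genes rose.

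Across 17549 genes, 2863 were higher and 2589 lower after irradiation (5452 by edgeR, 6767 by DESeq2), and the count was 4036, 3257, 3246, 3602 and 3242 without proliferating replicates 1 and 2 and irradiation replicates 1, 2 and 3 in turn. Without proliferating replicate 2, 1463 were higher and 1794 lower, so that the balance turned. The irradiation libraries are labelled paired-end and the others single-end, and the ribosomal transcript RNA45S5 held 14.4%, 20.1% and 13.5% of their counts against at most 1.63% in the other 10 libraries of that table. Genes with over 50% shared 48-base stretches were called higher in 411 and lower in 54 of 930 cases (44.2%), and other genes in 2452 and 2535 of 16619 (14.8%). Upper-quartile scaling moved the median of all genes from 0.06 to 0.27 and gave 3397 higher and 1913 lower genes, and with only the genes that share few stretches 3356 were called and the contractile list lost its camera call.

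**Figure D2:**
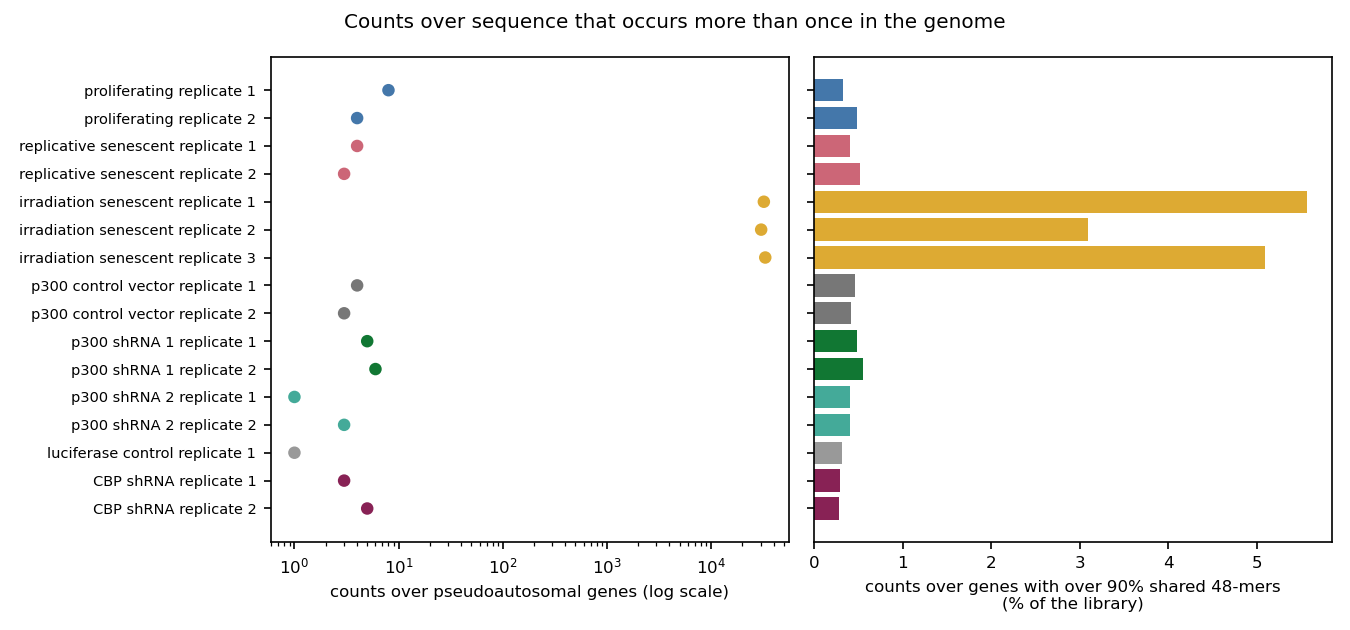
Sum of counts over pseudoautosomal genes on a log axis, and percent of counts over genes with more than 90% shared 48-base stretches, for each library. The 3 irradiation libraries held 32242, 30376 and 33259 pseudoautosomal counts, and each of the other 13 held at most 8.

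The kinds of senescence were compared directly to ask which changes differ between them. Irradiated cells had more IL6, CXCL5, IL1B and the prostaglandin synthase gene PTGS2 than replicatively senescent cells, and less CDKN2A. The interferon-stimulated genes SAMD9L, PARP9 and OAS2 and the contractile gene ACTA2, with its inducer TGFB2, were lower after irradiation. LMNB1, MKI67 and CDKN1A did not pass a test of the difference.

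IL6 stood at 179 ± 17.5 CPM after irradiation (n = 3) and 26.9 ± 4.03 CPM in replicative senescence (n = 2; log2 fold change 2.74, SE 0.51, adjusted p = 0.00413 by edgeR), and CDKN2A at 8.06 ± 2.50 against 30.8 ± 2.11 CPM (log2 fold change -1.93, SE 0.57, adjusted p = 0.0266). CDKN1A (1.00, SE 0.46, adjusted p = 0.117), LMNB1 (-0.65, SE 0.47, adjusted p = 0.311), MKI67 (-1.66, SE 0.90, adjusted p = 0.184), EP300 (-0.24 (SE 0.86)) and CREBBP (-0.14 (SE 0.61)) did not pass. CDKN2A lost its call in each fit with 1 library left out, IL6 lost it without replicative senescence replicate 2, and PTGS2 and MMP1 lost theirs without either replicative senescence library. The gene-naming rule again gave genes with shared stretches among the largest increases: SLC25A6 (at least 5670-fold) and CD99 (at least 8317-fold) had 0 counts in replicative senescence, and NBPF11, SMG1P1 and PKD1P1, each with over 50% shared stretches, followed and are uncertain. The largest decreases were in ATP5EP2 (-6.17), TRIM58 (-5.94), ATP5E (-4.52), the transcription factor FOS (-4.26), the phosphodiesterase PDE10A (-4.14) and the oxygen sensor EGLN3 (-4.10). Among genes with few shared stretches, chosen after the values were seen, AREG (8.92 (SE 0.62)), CXCL5 (7.40 (SE 0.60)), CCL20 (7.17 (SE 0.75)) and IL1B (6.66 (SE 1.19)) rose.

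Of 33 secreted cytokine and chemokine genes, 22 were higher after irradiation and 0 lower (24 adjusted over the list alone; median 2.83; camera adjusted p = 8.68e-08, adjusted p = 0.0800 with an estimated correlation). Of 23 NF-kB targets, 9 were higher and 1 lower, also when adjusted over the list alone, among them TNFAIP6 (3.72 (SE 0.55)) and PTGS2 (3.16 (SE 0.70); median 1.11; camera adjusted p = 0.0426, adjusted p = 0.355 with an estimated correlation). Of 41 interferon-stimulated genes, 4 were higher and 14 lower (5 and 15 adjusted over the list alone), with SAMD9L at -3.08 (SE 0.28), PARP9 at -1.77 (SE 0.23) and OAS2 at -2.31 (SE 0.31) (median -0.77; camera adjusted p = 0.0187, adjusted p = 0.951 with an estimated correlation, fry adjusted p 0.0510). Of 24 contractile and YAP targets, 1 was higher and 11 lower, also when adjusted over the list alone, with ACTA2 at -3.28 (SE 0.54) and TGFB2 at -2.44 (SE 0.39) (median -0.93; camera adjusted p = 0.00463, adjusted p = 0.352 with an estimated correlation). Of 46 mitosis genes, 0 were higher and 8 lower, among them KIF23 (-1.52 (SE 0.27)) and CENPE (-2.28 (SE 0.46); median -0.73; camera adjusted p = 0.0187, adjusted p = 0.951 with an estimated correlation, fry adjusted p 0.501). CENPE lost its call without replicative senescence replicate 2. Of 25 protease genes, 7 were higher and 0 lower, among them MMP1, at 832 against 46.7 CPM (camera adjusted p = 0.0932). Of 29 p53 targets, 4 were higher, among them GDF15 (3.27 (SE 0.62)), which lost its call without replicative senescence replicate 1. Without a camera call, 6 of 46 replication genes were higher, 3 of 41 histone genes were higher and 3 lower, 1 of 34 lamina genes higher and 3 lower, 1 of 20 acetyltransferase genes higher and 6 lower (KAT2B -2.69 (SE 0.52)), 1 of 35 matrix genes higher and 8 lower, and 2 of 8 kinase inhibitors lower. The remaining counts were 3 of 27 cholesterol genes higher, 4 of 38 lysosome genes higher and 1 lower, 2 of 27 unfolded protein response genes higher, 2 of 21 NRF2 targets lower, 5 of 29 immediate early genes higher and 6 lower, and 7 of 31 ribosome biogenesis genes higher and 2 lower. Of the markers, 1 of 16 fibroblast genes was higher and 2 lower, 1 of 12 epithelial genes higher and 2 lower, 0 of 6 endothelial genes passed, 2 of 7 leukocyte genes were higher, and 2 of 9 smooth muscle genes were higher and 1 lower.

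Across all genes, 2890 were higher and 2348 lower after irradiation than in replicative senescence (5238 by edgeR, 6531 by DESeq2). Upper-quartile scaling moved the median of all genes from 0.05 to 0.35 and gave 3637 higher and 1480 lower genes, and removing trends of gene length and GC content gave 2217 and 1235, a higher share of 64.2% against 55.2%. The count was 1547 and 1789 without replicative senescence replicates 1 and 2, and 2667, 3084 and 2772 without irradiation replicates 1, 2 and 3. The paired-end label of the irradiation libraries cannot be separated from irradiation here, and with few-shared genes alone the contractile list lost its camera call.

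Genes changed in both kinds of senescence, each against proliferating cells, numbered 551 in the same direction (179 higher, 372 lower) and 15 in opposite directions, where independence would give 52.9 and 74.4. The shared increases include OAS1, OAS2 and TIGAR, and the shared decreases LMNB1, KIF11, BUB1B, MCM3 and GRIA4. Over all genes the fold changes of both comparisons had a covariance of 1.01, against 0.258 in 20 simulations with no true change and shared controls, and a correlation of 0.390 against 0.569. The same 2 proliferating libraries served in both comparisons and are too few to be split, so part of the excess may come from shared controls. The shared count fell to 41 without replicative senescence replicate 1, 233 without replicative senescence replicate 2, 256 without proliferating replicate 1, and 336, 329 and 319 without irradiation replicates 1, 2 and 3.

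**Figure D3:**
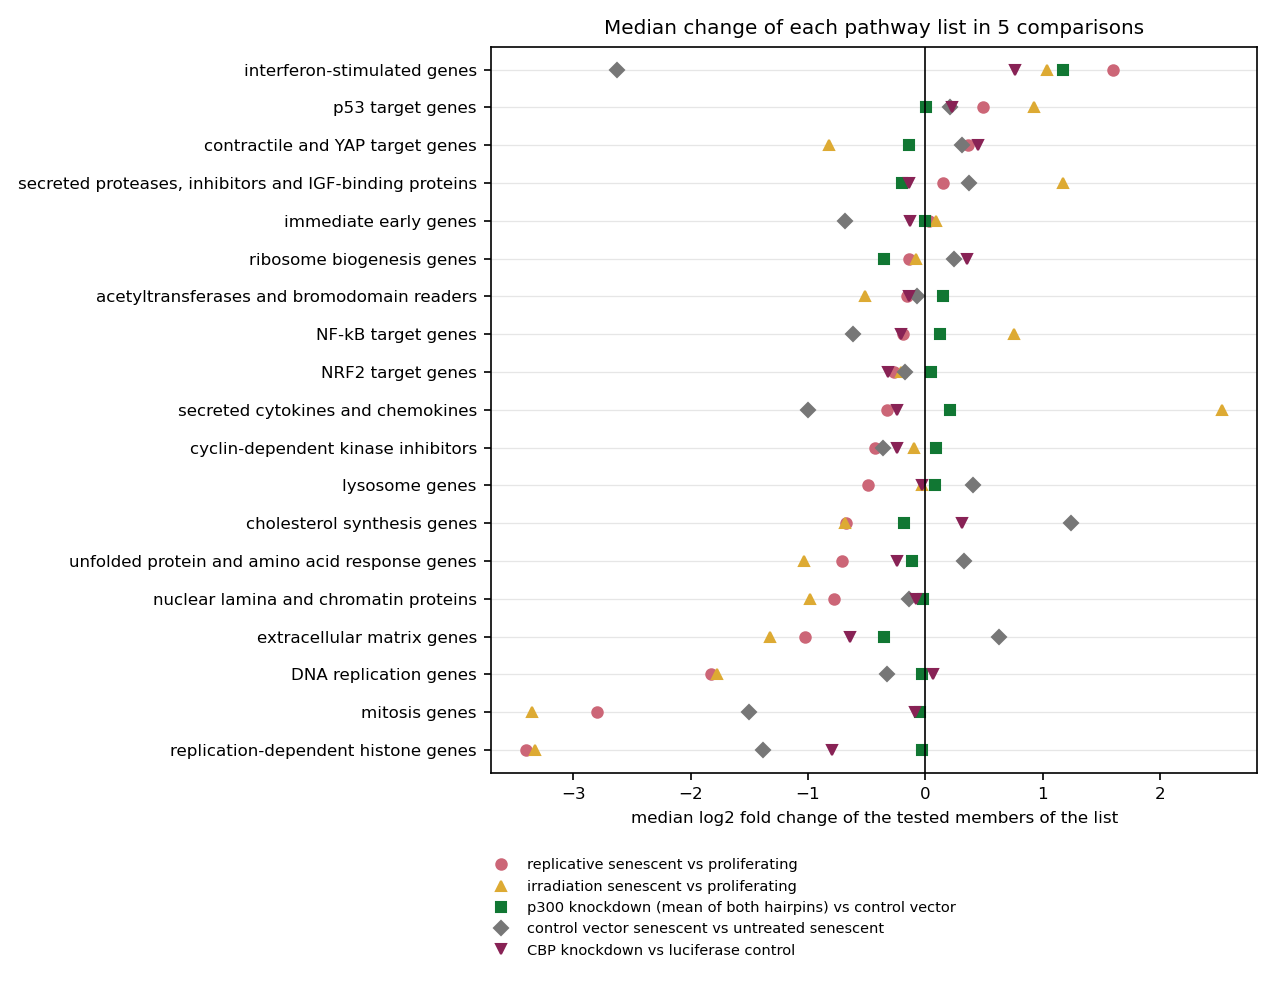
Median log2 fold change of the 19 pathway lists in 5 comparisons, 1 point per list and comparison. The cytokine list had a median of 2.53 after irradiation and -0.32 in replicative senescence, each against proliferating cells, and cell-cycle lists were below 0 in both.

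The p300 hairpins were compared with the control vector in senescent cells to ask which genes depend on p300. With the replicate numbers as blocks, the interferon-stimulated genes OAS2 and IFI44 and the chemokine gene CXCL11 were higher in the mean of both hairpins. The control vector libraries they were compared with stood below untreated senescent cells in OAS2 (1.30 against 19.3 CPM) and IFI44 (1.87 against 35.3 CPM), and in the interferon list by a median of -2.62. As a list, interferon-stimulated genes held with an estimated correlation with hairpin 2 and not with hairpin 1 or the mean. The endothelin receptor gene EDNRB was higher with each hairpin, and the carboxypeptidase gene CPA4 was lower in the mean of both. CDKN2A, CDKN1A, LMNB1, IL6 and MKI67 passed no test. With hairpin 1 the immediate early genes FOS, FOSB and JUNB were higher.

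Without the block, edgeR called 0 genes with hairpin 1, 0 with hairpin 2 and 0 for the mean of both. At an unadjusted p under 0.05 there were 1799, 638 and 995 genes, where 877 are expected, and DESeq2 called 349, 12 and 55. The replicate numbers pair the p300 and control vector libraries: replicate 1 and replicate 2 are labelled with the same population doublings in each arm (78 and 75), and the libraries' deviations from their arm's mean correlated between arms at 0.769, 0.718 and 0.723 over 11727 genes. With the p300 libraries blocked by number, a choice made after seeing the data, edgeR called 82 genes higher and 101 lower with hairpin 1 (108 and 84 with length and GC trends removed as well, so that the balance turned), 6 higher and 0 lower with hairpin 2, and 14 higher and 10 lower for the mean, whose balance turned with blocks in the untreated arms too (21 and 23) and by DESeq2 (27 and 28). In a blocked fit of the p300 libraries alone the counts were 74, 0 and 6. A blocked fit without the library labelled p300 shRNA 1 replicate 2 leaves a single hairpin 1 library. Its counts cannot show how far the calls rest on that library. Every direction given for hairpin 1 or for the mean rests in part on that library, in which EP300 stood above its control.

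EP300 itself did not pass: in the blocked fit its log2 fold change was -0.02 (SE 0.56) with hairpin 1, -1.19 (SE 0.56) with hairpin 2 and -0.61 (SE 0.47) for the mean, and without the block -0.40 (SE 0.95), -1.15 (SE 0.96) and -0.78 (SE 0.80). CREBBP stood at 0.64 (SE 0.60) for the mean. Against the control of the same number, CREBBP was higher with hairpins 1 and 2 (84.0 and 98.1 against 63.6 CPM, and 44.6 and 31.9 against 19.4 CPM). LMNB1 was higher in each case too (4.86 and 4.50 against 3.36 CPM, and 6.29 and 7.26 against 4.48 CPM). CDKN2A and IL6 went both ways. CDKN1A was lower with hairpins 1 and 2 in replicate 1 (331 and 282 against 763 CPM) and with hairpin 2 in replicate 2 (262 against 397 CPM). In the same libraries MKI67 was higher, with hairpin 1 only slightly (19.7 and 41.9 against 19.5 CPM, and 7.84 against 3.78 CPM). Both went the other way in the library labelled p300 shRNA 1 replicate 2 (CDKN1A 632 and MKI67 2.10 CPM), where EP300 stood above its control. Both hairpins of a number share a single control library. For the mean without the block, CDKN2A was at -0.07, SE 0.54, adjusted p = 1.00, CDKN1A at -0.68, SE 0.41, adjusted p = 0.926, LMNB1 at 0.55, SE 0.47, adjusted p = 0.982, IL6 at 0.15, SE 0.45, adjusted p = 1.00 and MKI67 at 0.50, SE 0.89, adjusted p = 1.00, as log2 fold changes by edgeR. In the blocked fit 3 genes were called with each hairpin: IFI44 (2.06 with hairpin 1, adjusted p = 0.0227, and 2.37 with hairpin 2, adjusted p = 0.0421), CXCL11 (4.06 and 3.99) and EDNRB (3.97 and 2.90). Independence would give 0.028 shared genes, but both hairpins were compared with the same control vector libraries, so these comparisons are not independent. Those control libraries stood below untreated senescent cells in IFI44. Over all genes the hairpins correlated at 0.367 in that fit, below the 0.502 that shared controls alone gave in simulations with no true change. The covariance was 0.248 against 0.147. In the planned fit without the block it was 0.256 against 0.247 (SD 0.009 over 20 simulations), close to what shared controls alone gave. The correlation there was 0.374 against 0.498. The other 3 genes called with hairpin 2 were the antiviral genes RSAD2 (3.29 (SE 0.45)) and OAS2 (2.57 (SE 0.28)) and XAF1 (2.51 (SE 0.29)), which shares 69.6% of its stretches and is uncertain. For the mean, the largest blocked increases included the pigment gene TYRP1 (2.96 (SE 0.49)), CXCL11 (4.03 (SE 0.38)), IFI44 (2.22 (SE 0.31)) and OAS2 (1.86 (SE 0.25)), and the largest decreases CPA4 (-2.43 (SE 0.40)), the nucleotide synthesis gene PRPS1 (-1.61 (SE 0.24)) and the cathepsin gene CTSZ (-1.57 (SE 0.25)). With hairpin 1 the largest blocked increases were in TYRP1 (3.78 (SE 0.53)), DLL4 (3.44 (SE 0.31)) and COLGALT2, and the largest decreases in SERPINA9 (-3.74 (SE 0.58)), CPA4 (-2.89 (SE 0.51)) and MGARP. FOS (2.55, SE 0.32, adjusted p = 0.00899), the kinase inhibitor gene CDKN1C (2.19, SE 0.35, adjusted p = 0.0237) and the cyclin gene CCNE1 (-2.08, SE 0.41, adjusted p = 0.0437) were also called with hairpin 1.

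Of 41 interferon-stimulated genes, without the block 0 passed over all genes with either hairpin or the mean. Adjusted over the list alone, 5 were higher with hairpin 1, 19 with hairpin 2 and 13 for the mean, and 0 were lower. The list's medians were 0.67, 1.37 and 1.17, and camera's adjusted p was 1.46e-05, 2.36e-35 and 1.27e-21. With hairpin 2 the list call held (adjusted p = 0.0172 with an estimated correlation), and with hairpin 1 and the mean it was lost (adjusted p = 0.518 and 0.0705 with an estimated correlation). In the blocked fit 3, 5 and 6 members passed and the estimated-correlation p became 0.462, 0.0165 and 0.0527. Of the other lists, camera called hairpin 1's mitosis (median -0.51), ribosome biogenesis (-0.50) and contractile genes (-0.55), each lost again (adjusted p = 0.898, 0.326 and 0.338 with an estimated correlation). With hairpin 2 it called proteases (-0.33), NF-kB targets (0.20), mitosis (0.35) and unfolded protein response genes (-0.43), also lost (adjusted p = 0.919, 0.347, 0.919 and 0.614 with an estimated correlation), and for the mean ribosome biogenesis genes (-0.36; adjusted p = 0.478 with an estimated correlation). The cytokine list had medians of 0.81, 0.08 and 0.21, with 0 of 33 members called in any of the 3.

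Of the cell-type markers, 0 members passed with either hairpin or the mean by edgeR over all genes with or without the block. With unscaled library totals, epithelial markers summed to 75.3 and 91.0 CPM with hairpin 1 against 240.2 and 217 CPM in the control vector libraries of the same numbers and 140.8 and 240.25 CPM with hairpin 2. Endothelial markers summed to 143.7 and 96.2 CPM with hairpin 1, 99.8 and 64.1 CPM in the control and 122 and 12.8 CPM with hairpin 2. Smooth muscle and pericyte markers summed to 772 and 420.4 CPM with hairpin 1, 709.6 and 471 CPM in the control and 746 and 1125 CPM with hairpin 2.

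The senescence genes were then followed under the knockdown to ask whether p300 keeps them changed. Of the 324 genes higher in replicative senescence, 198 (61.1%) moved down in the mean of both hairpins, with a median of -0.18 (fry p 0.159), and of the 504 lower genes 327 (64.9%) moved up, with a median of 0.18 (fry p 0.169), while other genes had a median of -0.01. Camera with a preset correlation gave 0.00283 and 8.94e-05, neither of which held (p = 0.143 and 0.193 with an estimated correlation). With hairpin 1 alone the higher set had a median of -0.23 (fry p 0.0431, and p = 0.0568 with an estimated correlation), a call that was lost with blocks (fry p 0.0547, and p = 0.128 with an estimated correlation), and with hairpin 2 alone -0.08 (fry p 0.867). Without control vector replicate 2 the median of the higher set under the mean was -0.05. The genes of irradiation senescence went apart between the hairpins: with hairpin 1 the higher set had a median of 0.09 and the lower set -0.07 (fry p 0.122 and 0.521), and with hairpin 2 -0.16 and 0.17 (fry p 0.0679 and 0.0613, and p = 0.0524 and 0.0264 with an estimated correlation). With p300 blocks the fry p with hairpin 2 was 0.0317 for the higher set, now past the threshold, and 0.0528 for the lower (p = 0.0530 and 0.0462 with an estimated correlation). With the planned blocks in the untreated and p300 arms it was 0.0449 and 0.0369 (p = 0.0775 and 0.0384 with an estimated correlation). The difference between the hairpins had medians of 0.25 and -0.23 (fry p 0.00517 and 0.0225, and p = 0.0323 and 0.0218 with an estimated correlation), and with blocks in the untreated and p300 arms the higher set was lost (p = 0.0547 with an estimated correlation). In the CBP libraries the higher set had a median of 0.47 over 278 genes (fry p 0.681) and the lower set -0.30 over 459 genes (fry p 0.66). The replicative senescence sets were called on replicatively senescent and proliferating libraries, and the irradiation sets on irradiated and proliferating libraries. None of these libraries enters the knockdown contrasts. The irradiation sets were not tested with length and GC trends removed or with few-shared genes alone. Expression in the irradiation libraries correlated with GC content at 0.52, 0.43 and 0.52, and 411 of the 2863 higher genes share many stretches. Part of the movement of these sets may thus come from such trends, which cannot be told apart here.

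**Figure D4:**
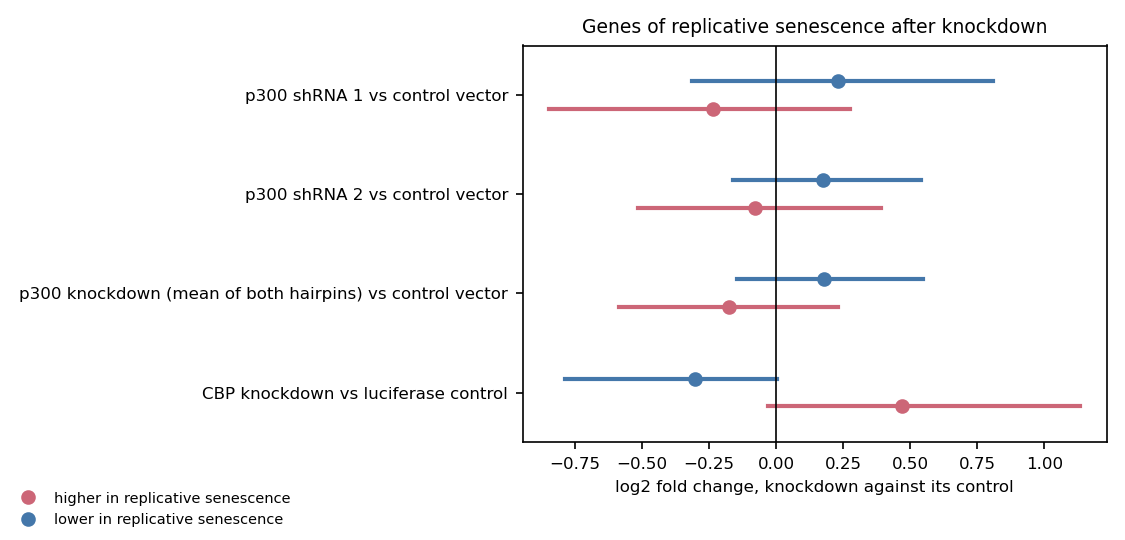
Median (point) and 25th to 75th percentile (line) of the log2 fold change of the genes higher and of the genes lower in replicative senescence, under p300 hairpin 1, hairpin 2, their mean and CBP knockdown. The medians under the mean of both hairpins were -0.18 and 0.18.

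The hairpins were compared with each other to see how far they share an effect. Without the block 0 genes passed by edgeR (2008 at an unadjusted p under 0.05, 433 by DESeq2), and with it 64 were higher and 75 lower with hairpin 1 than with hairpin 2 (84 and 82 with length and GC trends removed as well). The count was 0 in a blocked fit of the p300 libraries alone, so the genes named here rest on a spread estimated from all groups. They also rest in part on the library labelled p300 shRNA 1 replicate 2, without which a single hairpin 1 library is left. In the blocked fit, the contractile genes MYH11 (-4.55 (SE 0.90)), CNN1 (-2.04 (SE 0.36)) and ANKRD1 (-2.58 (SE 0.51)) and the natriuretic peptide gene NPPB (-5.52 (SE 1.12)) were lower with hairpin 1. The sulfatase gene SULF2 (3.84 (SE 0.70)), SCG2 (3.13 (SE 0.40)) and FOSB (2.44 (SE 0.31)) were higher, and OAS2 was lower (-1.43, SE 0.26, adjusted p = 0.0401). EP300 itself did not pass (1.18, SE 0.56, adjusted p = 0.268). The contractile list had 0 of 24 members called without the block and 8 lower adjusted over the list alone (median -0.92; camera adjusted p = 1.38e-05, adjusted p = 0.189 with an estimated correlation). The mitosis list (median -1.03; adjusted p = 0.525 with an estimated correlation) and the interferon list (median -0.53; adjusted p = 0.431 with an estimated correlation) had lost calls too. So had the DNA replication (median -0.26), lamina (-0.28), cholesterol (-0.48), NRF2 (-0.29), ribosome biogenesis (-0.32) and immediate early lists (0.33), with an adjusted p between 0.283 and 0.708 with an estimated correlation. Without p300 shRNA 2 replicate 1 the unblocked count was 50, against 0 with all libraries.

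Hairpin 1 (CAGACAAGTCTTGGCATGGTA) matched EP300 with 0 mismatches in exon 2 of 31, in coding sequence, at chromosome 22 positions 41117285 to 41117305 of GRCh38. Hairpin 2 (TACACTAGAGACACCTTGTAT) matched exon 31 of 31 at positions 41178949 to 41178969, across the border of the stop codon and the 3′ UTR, with 1 mismatch, T21G, counted from the 5′ end of the hairpin target with the hairpin's base first. In hairpin 2's fold changes the 1317 genes with a match to its seed in the 3′ UTR lay at percentile 0.411 of all 7-base words, with a mean difference of -0.036.

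The control vector libraries were compared with untreated senescent cells to see how far they stand apart. Virus, selection, passage and batch cannot be told apart in this comparison. Interferon-stimulated genes were lower in the vector libraries: OAS2, PARP9, MX2, IFI44 and HERC6 fell. PARP12 and the antisense transcript SBF2-AS1 also fell. IL6 did not pass.

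IFI44 stood at 1.87 against 35.3 CPM (log2 fold change -4.24, SE 0.54, adjusted p = 0.0290 by edgeR) and OAS2 at 1.30 ± 0.305 against 19.3 ± 2.54 CPM (log2 fold change -3.88, SE 0.39, adjusted p = 0.0131, SD, n = 2 each). MX2 (-3.40 (SE 0.39)), PARP9 (-2.38 (SE 0.26)), HERC6 (-2.69 (SE 0.37)), PARP12 and SBF2-AS1 (-3.38 (SE 0.43)) also fell. IL6 stood at 4.54 ± 1.32 against 26.9 ± 4.03 CPM (log2 fold change -2.56, SE 0.54, adjusted p = 0.157), and CDKN2A at -0.53, SE 0.63, adjusted p = 0.896. In all 0 genes were higher and 7 lower, 1365 had an unadjusted p under 0.05, and DESeq2 called 68 higher and 170 lower. The blocked fit sets the fitted level of vector replicate 1 against the mean of both untreated libraries, so it is not the same comparison. It called 350 higher and 604 lower, IL6 among them (adjusted p = 0.0272 by edgeR). With length and GC trends removed as well it called 468 higher and 342 lower, so that the balance turned. The count was 5 without replicative senescence replicate 1 and 0 without replicative senescence replicate 2, control vector replicate 1 or control vector replicate 2. Of 41 interferon-stimulated genes, 5 fell over all genes and 32 adjusted over the list alone, with a median of -2.62, and the camera call (7.37e-48) held with an estimated correlation (adjusted p = 0.00683 with an estimated correlation). The NF-kB list had 0 of 23 called and 2 lower adjusted over the list alone, with a median of -0.62 and an adjusted p = 0.00926 with an estimated correlation. The cytokine (adjusted p = 0.0653 with an estimated correlation), immediate early (median -0.69, adjusted p = 0.0653 with an estimated correlation) and mitosis lists (median -1.50, adjusted p = 0.239 with an estimated correlation) lost their camera calls. The histone (median -1.38, 19 of 41 lower adjusted over the list alone), DNA replication (-0.33), lamina (-0.14), cholesterol (1.24), lysosome (0.40), contractile (0.31) and ribosome biogenesis lists (0.24) lost theirs too, with an adjusted p between 0.239 and 0.630 with an estimated correlation. Population doublings in the labels were 78 and 79 for the untreated and 78 and 75 for the vector libraries.

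CBP knockdown was compared with the luciferase hairpin to set the related acetyltransferase beside p300. CREBBP did not pass, and neither did any other gene. The largest list medians were an increase of interferon-stimulated genes and a decrease of histone genes, neither of which held. The control was a single library, assumed to vary like the knockdown libraries.

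CREBBP had a log2 fold change of -0.69 (SE 0.40) with an unadjusted p of 0.147 by edgeR, EP300 -0.14 (SE 0.43), CDKN2A 0.37 (SE 0.47), CDKN1A -0.24 (SE 0.41), LMNB1 -0.10 (SE 0.67), IL6 -0.10 (SE 0.99) and MKI67 -0.28 (SE 0.69). The CBP libraries lay on opposite sides of the control in IL6 (41.4 and 7.31 against 26.1 CPM), LMNB1 (14.6 and 5.57 against 10.8 CPM) and MKI67 (54.7 and 18.7 against 44.5 CPM). Of 14453 tested genes edgeR called 0, with 30 at an unadjusted p under 0.05 where 723 are expected, and DESeq2 called 0. The interferon list had a median of 0.76 over 39 genes and the histone list -0.79 over 39. Their camera adjusted p was 1.22e-06 and 4.85e-13, and both were lost (adjusted p = 0.809 and 0.809 with an estimated correlation). None of the camera calls in this comparison held with an estimated correlation. The matrix list had a median of -0.64, the fibroblast markers -0.66, the cytokines -0.25 and the contractile genes 0.45. The fibroblast markers summed to 15710 and 8266 CPM in the CBP libraries and 19190 CPM in the control, here with unscaled library totals. The mitochondrial ribosomal RNA RNR2 held 14.5% of counts in the luciferase library and 15.9% and 28.3% in the CBP libraries.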

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

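The tests of explanations in this part were chosen after the results had been seen, except the test of the hairpin 1 seed, and so was the block in the p300 arms. The tests of differences between groups were planned.

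Irradiation and replicative senescence libraries differed in 5238 genes by edgeR's test of the difference, each against the same proliferating cells. Library type goes with irradiation, so part of this count may come from it. Expression relative to the mean of all libraries correlated with GC content at 0.52, 0.43 and 0.52 in the irradiation libraries. It did so at -0.09 and -0.14 in proliferating and -0.23 and -0.24 in replicatively senescent libraries. With length and GC trends removed, 2217 genes were higher and 1235 lower after irradiation. CDKN2A differed by -1.93 (log2, irradiation minus replicative senescence) and IL6 by 2.74. The cytokine list differed by a median of 2.83, the NF-kB targets by 1.11 and the contractile and YAP targets by -0.93. In the blocked fit 139 genes differed between hairpin 1 and hairpin 2, and 0 in a blocked fit of the p300 libraries alone.

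Genes that share many 48-base stretches with other genes were higher in the irradiation libraries. The lowest pseudoautosomal sum in an irradiation library was 30376 counts and the highest elsewhere 8, so a candidate explanation is that reads matching several genome positions were counted in these libraries only. A trend of length and GC content is not the whole cause, since 83.5% of the genes concerned were still called higher with the trends removed. A response to irradiation cannot be told apart from the library type, since all 3 libraries share both, although only 6 such genes were called higher in replicative senescence. With few-shared genes alone, 3139 genes still differed between the kinds of senescence.

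EP300 stood above its control in the library labelled p300 shRNA 1 replicate 2. An exchange with the hairpin 2 library is argued against by a correlation over genes of 0.603 between replicates in the difference of hairpins. An exchange with the control is argued against by a correlation of 0.503 in hairpin 1 minus control (11726 genes, which are not independent replicates). The same correlation was 0.169 for hairpin 2 minus control, although hairpin 2 had EP300 below its control in both replicates. With length and GC trends removed the log2 ratio of EP300 in the library labelled p300 shRNA 1 replicate 2 was 0.22. Its standard error was 1.01 for 1 library against 1, so a trend may explain part of it and cannot be told apart. A weak knockdown in that culture stays open at the measured log2 ratio of 0.52, and single libraries with a spread of this size do not decide.

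More genes were called with hairpin 1 than with hairpin 2 in the blocked fit (183 and 6). Leaving out the library labelled p300 shRNA 1 replicate 2 cannot show whether the pattern rests on it. It leaves a single hairpin 1 library, and the blocked fit without the other hairpin 1 library was not run. Seed matches of hairpin 1 in 3′ UTRs are argued against: the 1642 genes with the match lay at percentile 39.0 among 15796 7-base words, counted from the most lowered. The number of calls with hairpin 1 did not fall when length and GC trends were removed, with 192 genes called after removal and 183 before. The balance of higher and lower genes turned, and it was not tested whether the same genes were called. A trend thus stays open for which genes were called. A stronger loss of EP300 mRNA with hairpin 1 was not decided: EP300 was higher with hairpin 1 by 1.18 on the log2 scale (unadjusted p 0.0599 by edgeR). Hairpin 2's own seed match lay at percentile 0.411 in hairpin 2's fold changes, so a small seed effect of hairpin 2 may be present (mean log2 difference -0.036).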

How the results depend on the processing

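The alternatives with only few-shared genes, with length and GC trends removed (alone or joined to another choice) and with blocks in the p300 arms only were chosen after seeing the data, and the others were planned. No named gene or list that was called changed sign in the settings checked. For named genes these were RLE scaling, DESeq2, the filter at 1 CPM, only the compared groups, blocks, and 1 library left out. For lists they were RLE scaling, blocks, few-shared genes alone and the other set tests. Neither was checked with length and GC trends removed, upper-quartile scaling, no filter on low counts, or the 50 highest-count genes left out. The balance of higher and lower genes turned for replicative senescence without replicative senescence replicate 1 (39 and 9), for irradiation without proliferating replicate 2 (1463 and 1794), and, against the same blocked fit without trend removal, with p300 blocks and trend removal together for the control vector (468 and 342), hairpin 1 (108 and 84) and hairpin 1 against hairpin 2 (84 and 82). For the mean of both hairpins it was 14 and 10 with p300 blocks, 21 and 23 with blocks in both arms and 27 and 28 by DESeq2. Counts not named here stayed within 1.5 times of the reported counts without blocks. Of the planned checks on named genes 6791 stayed on their side, 248 became weaker, 299 stronger and 157 moved. Leaving out each library in turn was not possible for CBP knockdown, where no residual degrees of freedom remain, and its count stayed 0 under the 7 other settings.

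Replicate numbers were used as blocks. With them in the p300 arms only, the counts were 2554 for replicative senescence, 8604 for irradiation, 8514 between the kinds of senescence, 183 with hairpin 1, 6 with hairpin 2, 24 for the mean, 139 between hairpins and 954 for the control vector. With blocks in the untreated arms too they were 3199 for replicative senescence, 506 with hairpin 1, 9 with hairpin 2, 44 for the mean, 491 between hairpins and 345 for the control vector. The pairing of the untreated libraries is not shown. In the control vector comparison the p300 blocks set the fitted level of vector replicate 1 against the mean of both untreated libraries. With blocks in the untreated arms too, it is replicate 1 against replicate 1. Irradiation is then also set against the fitted level of replicate 1 of the untreated arms. These counts are thus not blocked versions of the comparisons made without blocks. Trend removal joined to the p300 blocks gave 2859, 192, 6, 21, 166 and 810 for replicative senescence, hairpin 1, hairpin 2, the mean, between hairpins and the control vector. Genes shared by both kinds of senescence became 1466 with p300 blocks and 1674 with both, and genes shared by both hairpins 3 and 5. Without the library labelled p300 shRNA 1 replicate 2 the p300 blocks leave a single hairpin 1 library, so counts of that fit are not compared. A blocked fit of the p300 libraries alone gave 74 with hairpin 1, 0 with hairpin 2, 6 for the mean and 0 between hairpins.

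DESeq2 gave 1989 for replicative senescence, 349 with hairpin 1, 12 with hairpin 2, 55 for the mean, 433 between hairpins, 238 for the control vector, 1166 genes shared by both kinds of senescence and 4 shared by both hairpins. The cause was not tested. Fitting only the compared groups gave 463 for replicative senescence, 11568 between the kinds of senescence and 0 for the control vector. Fewer libraries then estimate the spread, and the groups that share one estimate in the main fit differ in it. Chi-square per gene between replicates was 643 for proliferating and 134 for replicatively senescent libraries. It was 15.1, 78.6 and 92.1 for the irradiation pairs. Whether this accounts for the larger count was not tested. No filter on low counts gave 3 with hairpin 1 and 13 for the control vector, and leaving out the 50 highest-count genes gave 3 with hairpin 1. Upper-quartile scaling moved the median of all genes to 0.13 with hairpin 1, 0.18 between hairpins and 0.16 for the control vector, and trend removal to 0.17 for irradiation and 0.21 between the kinds of senescence. Removing length and GC trends gave 3452 between the kinds of senescence and 10 with hairpin 1. With only few-shared genes, where fewer genes are tested, the counts were 3356 for irradiation, 3139 between the kinds of senescence and 2 with hairpin 1, and with trends removed as well 2650, 1776 and 11.

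Leaving out 1 library in turn gave 48 to 637 for replicative senescence, 3242 to 4036 for irradiation and 1547 to 3084 between the kinds of senescence. It gave 0 to 1 with hairpin 1, 0 to 0 with hairpin 2, 0 to 1 for the mean, 0 to 50 between hairpins, 0 to 5 for the control vector and 41 to 443 for the genes shared by both kinds of senescence. Each such fit has fewer libraries. Where the library left out is 1 of 2, a single one stays in its group, and the count cannot show how far the calls rest on it. Of named-gene calls under these fits, 122 of 208 were kept in replicative senescence, 379 of 396 after irradiation, 316 of 413 between the kinds of senescence and 4 of 28 for the control vector.

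The replicative senescence sets under the mean of both p300 hairpins kept the sign of their medians, from -0.24 to -0.05 (lowest in size without control vector replicate 2) for the higher and from 0.13 to 0.33 for the lower set with 1 library left out. With hairpin 1 alone the higher set had a median of -0.23, now past the threshold (fry p 0.0431), and with blocks that call was lost (fry p 0.0547 and 0.0601). List calls were not recomputed with a library left out. Camera calls with few-shared genes alone were lost for the unfolded protein list in replicative senescence and with hairpin 2, and for the contractile list after irradiation, between the kinds of senescence, with hairpin 1 and for the control vector. With blocks in both arms the interferon and mitosis lists lost theirs between the kinds of senescence. There irradiation is set against the fitted level of replicative senescence replicate 1, which is another comparison. Depth was not varied. In the self-test 0% of 2-fold changes were called with hairpin 1 and 13.4% with blocks at the same depth.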

Other observations

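The symbol families in this part were chosen and tested after the results had been seen. Genes were grouped by the leading letters of their symbols (275 families). In replicative senescence 41 of 61 HIST genes were lower (median -2.93), and so were 6 of 12 MCM genes, 11 of 36 KIF genes and 6 of 44 COL genes (1 COL gene was higher), while 4 of 9 IFI genes, 2 of 17 KRT genes and 1 of 12 PSG genes were higher. After irradiation 9 of 12 PSG genes (pregnancy-specific glycoproteins; median 3.91) and 6 of 12 CXCL genes (median 3.01) were higher, and 20 of 36 KIF, 22 of 37 CEP and 11 of 22 NUP genes were lower, with 2 higher in each of these 3 families. Against replicative senescence, 8 of 18 MMP genes were higher after irradiation and 15 of 54 EIF genes lower (2 higher). None of these families held with an estimated correlation, with adjusted p values such as 0.836 for HIST in replicative senescence and 0.993 for PSG after irradiation.

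The families with the highest medians after irradiation were GOLGA (25 of 32 higher and 1 lower, median 6.02), NBPF (10 of 11, median 4.18) and NPIPB (9 of 9, median 6.73), of which 22, 9 and 9 members share over 50% of their 48-base stretches with other genes. PSG genes had 0 such members.

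Hairpin 2's own seed, CCTTGTA, stood at percentile 0.411 (rank 65 of 15796 words, 1317 genes) in hairpin 2's fold changes, with a mean difference of -0.036, against a mean difference of -0.0043 for hairpin 1's seed, GCATGGT, in hairpin 1's. Pooled over all groups, marker sums of other cell types ranged from 11.2 to 73.4 CPM for leukocytes, 50.6 to 240.25 for epithelium, 12.8 to 284 for endothelium and 373 to 1125 for smooth muscle in the libraries of the larger table.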
